A study of Mus musculus with 8 samples.

How the data were processed

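Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin. The samples were C57BL/6 mouse DN3 thymocytes, the stage of T-cell development at which the pre-T-cell receptor is selected, and leukaemia blasts. N-Me is the Notch-Myc enhancer, a distal element downstream of Myc. The mutant cells carried homozygous mutations at GATA sites 1 and 2 of this element. The series held 8 samples, of which 4 were DN3 libraries, 2 per genotype. The 4 T-cell leukaemia samples were not analysed here. The labels do not say whether replicates came from separate animals, so every p-value measures only the spread between these libraries or between regions within them.

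Each of the 4 libraries had its own broad peak list, so peaks had been called per library and not on pooled samples. Per the submitters' processing notes, the tools were cutadapt 1.16, Bowtie2 2.3.3.1, SAMtools 1.7 and MACS2 2.1.1, and the genome build was mm10 (GRCm38). The order, settings, read filters and any shift of reads for transposase binding are not given in the sources used here. In the deposited lists each peak carries a score, which is its −log10 q multiplied by 10 and truncated. The deposited fold enrichment is a ratio of the library's pileup to its local background, averaged over the peak by the authors' caller. The deposited −log10 p and −log10 q values describe each peak within its own library. The lowest −log10 q was 1 to 1.02 in the lists, a q threshold of about 0.1. Fold and −log10 values were used to describe, rank or filter peaks within a list. The exception is a comparison of −log10 p at matched fold between libraries, in the closing section. Peak lists hold no read counts, so the depth of each library is unknown, no count model was fitted, and no interval of an accessibility level could be given.

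The deposited lists differed in their construction. The shortest peak was 64 and 65 bp in the wild-type lists and 73 and 87 bp in the mutant lists. The smallest gap between neighbouring peaks was 257, 261, 293 and 349 bp, in each case 1 bp more than 4 times the shortest peak. Mutant lists therefore joined neighbouring peaks over longer gaps, and had a longer minimum peak length, than wild-type lists.

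Peaks on chromosomes 1 to 19, X and Y were used, which left out 0.112% to 0.131% of each list. Consensus regions were the merged union of the 4 lists. A library had a region if any of its peaks overlapped it by 1 bp or more. A region was called only in wild type when both wild-type libraries and no mutant library had it, and only in mutant in the mirror case. Gene positions came from a RefSeq gene table of the GRCm38.p6 assembly. This table gives no strand, so an annotated end of a protein-coding gene, at either side of the gene, took the place of the transcription start that had been planned. Regions within 1 kb of such an end are called gene-end regions, and all others distal. Exons and untranslated regions were not annotated. All 181 genes of 14 lists were matched by symbol. Regions were assigned to the gene with the nearest end within 50 kb. The Myc domain ran for 2 Mb from the annotated start of Myc, which lies on the plus strand. N-Me was taken as the region nearest to its published distance from Myc, among regions called in any library, within a window of 1.2 to 1.3 Mb.

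Shares of regions were compared with Fisher's exact test (two-sided), over all regions called in both libraries of a genotype, with Benjamini-Hochberg adjustment over the 14 lists. Intervals of shares are exact binomial (Clopper-Pearson) at 95%. Neighbouring regions are not independent replicates, so these tests describe these 4 libraries. The overlap of peak sets was the Jaccard index in bp. Comparisons of 2 against 2 libraries used an exact two-sided permutation test, which cannot give a p below 0.333 because 4 libraries split into pairs in only 3 ways. The code was tested on simulated lists of 60000 regions, in which it recovered 200 of 200 regions removed from the mutant lists and 150 of 150 removed from the wild-type lists. These lists were copies of peaks from the first wild-type list with jittered edges, so they do not test differences in depth, minimum length or joining. The exact stratified test gave p under 0.05 in 3% of 200 simulated sets with no effect, and a mean odds ratio of 4.12 over 20 sets simulated at 4.06. Set membership did not depend on the stratum in these sets, so they do not test the adjustment for strength. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

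The groups, gene lists, tests, named regions and the alternatives below were chosen before the data were examined. Named regions were N-Me and its window, all genotype-specific regions from 50 kb upstream of Myc to the end of its domain, and the 10 gene-end and 10 distal regions of each direction with the highest lower fold of the 2 libraries. List genes with an end called in 1 genotype only were also named. Of these regions, 2 are not reported here. Alternatives were peaks with −log10 q of at least 5, peaks with fold of at least 4, the same number of peaks from each list (119023, from the top by −log10 p) and a call only where peaks covered at least 50% of a region. Peaks were filtered before regions were called. A region called in 1 genotype only under such a filter may therefore hold a weaker peak of the other genotype. Further alternatives were autosomes only, each replicate left out, deciles of strength (the higher fold of the 2 libraries), assignment within 10 kb and gene ends within 500 bp. Added after the data were seen were lists given a common minimum length of 87 bp and joining gap of 348 bp, lists trimmed to the same covered length, and the Myc-domain test for regions called only in mutant. A comparison of GATA motif frequency was planned and not run, since it needs the genome sequence.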

Results

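ATAC-seq peak lists from 4 libraries of mouse DN3 thymocytes were compared, 2 with a wild-type Notch-Myc enhancer (N-Me) and 2 with homozygous mutations at its GATA sites 1 and 2. The wild-type lists held 169255 and 156372 peaks on the chromosomes used, covering 72.1 and 70.8 Mb. The mutant lists held 121022 and 119023 peaks, covering 72.3 and 69.3 Mb. Merging the lists gave 180321 consensus regions with a median width of 344 bp, of which 102231 (56.7%) were called in all 4 libraries. Read depth is not recorded in peak lists, so a region without a peak was not detected at the depth of that library.

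The first comparison asked whether the enhancer itself stayed open in DN3 cells when its GATA sites were mutated. N-Me was called in 4 of 4 libraries, as a region at chromosome 15, 63254999 to 63256647 (GRCm38), 1649 bp wide. It lies outside annotated genes, 1270 kb downstream of the start of Myc, the proto-oncogene that Notch activates through this element. The nearest annotated genes were the long non-coding RNAs Gm30159, 110 kb on the Myc side, and Gm41335, 96.6 kb on the far side, and the nearest protein-coding gene beyond it was Gsdmc at 519 kb. The main N-Me peak had the authors' fold enrichment of 6.45 and 5.67 in the wild-type lists, with −log10 q of 101.03 and 61.98. In the mutant lists its fold was 6.60 and 6.18, with −log10 q of 62.8 and 39.9. These values belong to each list and were not tested between genotypes.

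The outline of the N-Me peak differed between genotypes. Its left edge stood at 63255109 and 63254999 in wild type and at 63255284 and 63255334 in mutant. The closest libraries of the 2 genotypes were thus 175 bp apart, more than the 110 bp between wild-type and the 50 bp between mutant replicates. On the right, the wild-type lists ended the main peak at 63256106 and 63256098 and held a separate small peak with fold 1.84 and 2.03. The mutant lists had 1 continuous peak that ended at 63256520 and 63256564, and mutant lists joined peaks over longer gaps. Of 17160 shared peaks of like width, 2352 (13.7%) had an edge at least 175 bp apart between genotypes, in either direction. Outward shifts, which longer joining gaps can give, are among them.

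Around N-Me, the window from 1.2 to 1.3 Mb downstream of Myc held 4 other regions. The region from 63270083 to 63271741 and the region from 63279640 to 63280590 were called in all 4 libraries. A narrow region from 63269242 to 63269436 (195 bp) was called in both wild-type and no mutant library, with fold 2.53 and 2.69. The last, from 63261406 to 63261476, was called in wild type 1 only.

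**Figure D1:**
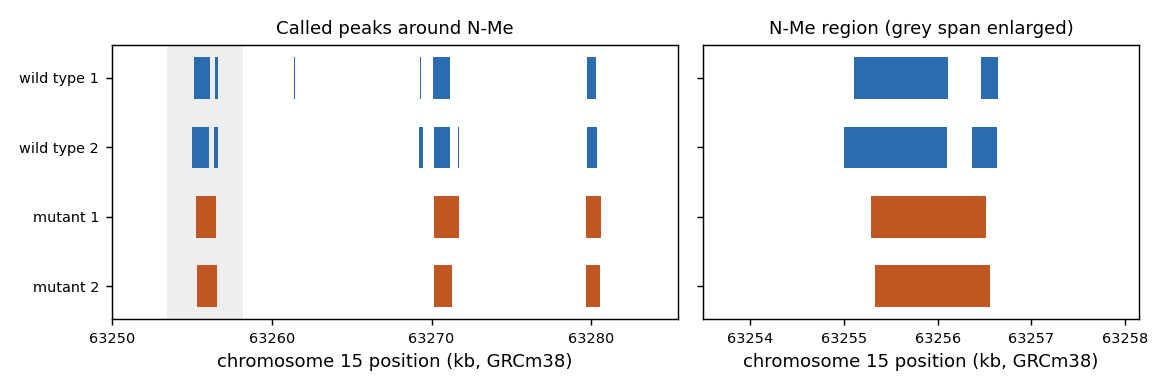
Peaks called in each of the 4 libraries (rows) along chromosome 15 (kb, GRCm38) around N-Me, with the grey span enlarged on the right; bars are called peaks, blue for wild type and orange for mutant. A peak lies at N-Me in 4 of 4 libraries, and its left edge in mutant is at least 175 bp inside that in wild type.

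Along the Myc domain, no excess of regions called only in wild type was detected. Of 105 regions called in both wild-type libraries within 2 Mb downstream of Myc, 14 (13.3%, 95% interval 7.49 to 21.4) were absent from both mutant lists, against 15% of the other 134860 regions (odds ratio 0.874, Fisher's exact p = 0.784). The start of the Myc gene carried a peak in 4 of 4 libraries. The 14 regions were spread over the domain, 6 between Myc and N-Me and 8 beyond N-Me. The strongest, from 63006550 to 63006698, lay 1021 kb from Myc and had fold 4.46 and 4.11. No region from 50 kb upstream of Myc up to its start was specific to a genotype. With peaks of fold 4 or more, with −log10 q of 5 or more, with equal numbers of peaks or with 50% cover, the odds ratio was above 1, at 1.06 to 1.42, with exact p of 0.41 to 0.777.

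In the opposite direction the domain held an excess. Of 102 regions called in both mutant libraries, 10 (9.80%, 95% interval 4.80 to 17.3) were absent from both wild-type lists, against 1.75% of the other 106898 (odds ratio 6.12, Fisher's exact p = 1.32e-05). All 10 lay between Myc and N-Me, at 240, 303, 408, 715, 750, 754, 796, 823, 883 and 1002 kb from the start of Myc. They were weak peaks, with fold from 1.57 to 2.88, and 156 to 498 bp wide. The test was added after the data were seen. The odds ratio was 3.11 without mutant replicate 1, 3.15 with 50% cover and 3.93 with equal numbers of peaks, and among peaks of fold 4 or more, which none of these 10 reached, 2 regions of the domain were called only in mutant (exact p = 0.0741).

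**Figure D2:**
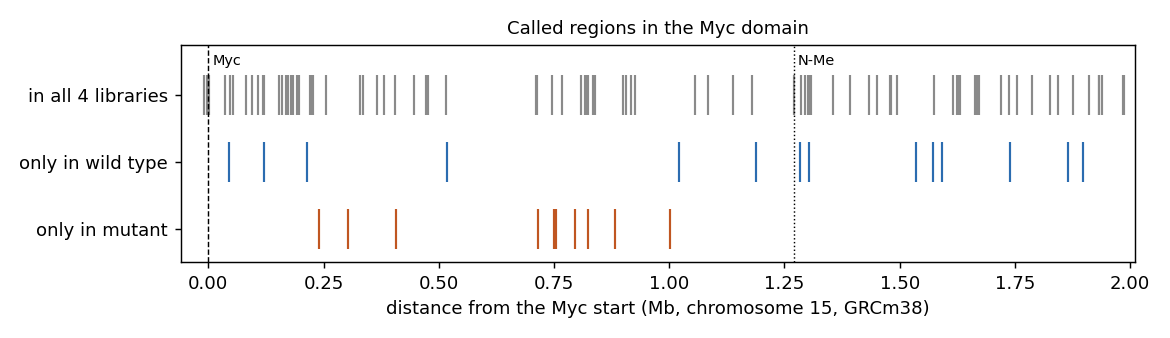
Regions called in all 4 libraries (grey), only in wild type (blue) and only in mutant (orange), by distance from the start of Myc (Mb); each line is 1 region, with dashed and dotted lines at Myc and N-Me. All 10 mutant-only regions lie between Myc and N-Me, while the 14 wild-type-only regions lie on both sides of N-Me.

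Genome-wide, 20194 regions were called only in wild type and 1876 only in mutant. They made up 15% of the 134965 regions of both wild-type libraries and 1.75% of the 107000 regions of both mutant libraries. Regions called only in wild type were narrow and weak, with a median width of 176 bp and a median lower fold of 2.36, against 608 bp and 3.36 (lowest fold) for regions called in all 4 libraries. The share called only in wild type was 44.6% in the weakest decile of regions and 0.089% in the strongest. These deciles were of the highest fold in any of the 4 libraries. Regions also called in mutant had more libraries in which to reach a high fold, which widens this contrast by construction. Splitting the libraries by genotype gave 22070 specific regions in all, against 2146 and 2225 for the other 2 ways of pairing them, and 3 splits cannot give a share below 0.333. With 119023 peaks from each list, which pushes the directions towards balance by construction, 5086 regions were called only in wild type and 7423 only in mutant. With equal covered length the counts were 16920 and 1478, and with 50% cover 21853 and 6901. Leaving out 1 library, which changes counts by construction, gave 26342 to 40864 and 2740 to 4940.

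**Figure D3:**
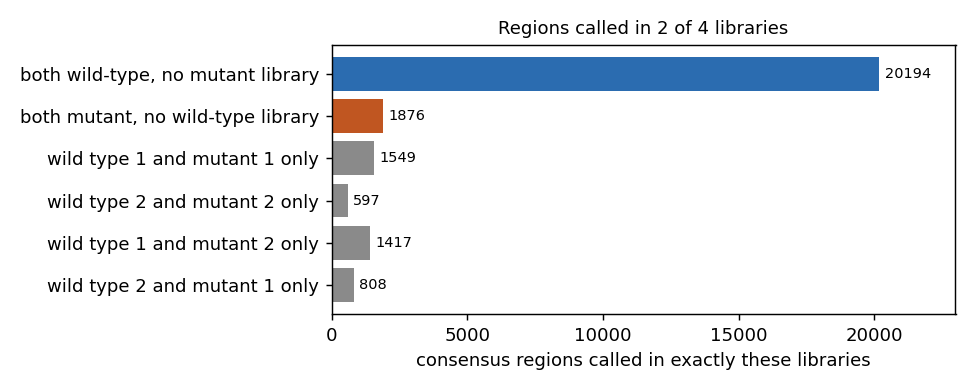
Number of consensus regions called in exactly 2 of the 4 libraries (bars from 0), for each pair of libraries. Pairs of the same genotype gave 20194 (wild type) and 1876 (mutant) regions, and mixed pairs 597 to 1549.

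Peak sets were more alike within than between genotypes. The Jaccard index was 0.764 between the wild-type lists and 0.786 between the mutant lists, and 0.666 to 0.681 for the 4 pairs across genotypes. Wild-type lists had 1.36 times as many peaks as mutant lists (162814 ± 9110 against 120022 ± 1414, SD, n = 2 each, exact permutation p = 0.333). Mutant peaks were wider, with a median of 444 and 421 bp against 284 and 302 bp (exact permutation p = 0.333, n = 2 each). The mutant lists had a longer minimum peak length and longer joining gaps, which alone make peaks fewer and wider. With both made common the ratio of peak numbers was 1.24, and no width is given here for that setting. The covered length was 71.5 ± 0.936 Mb in wild type and 70.8 ± 2.14 Mb in mutant (SD, n = 2 each, exact permutation p = 1). A p of 0.333 is the smallest this design allows.

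Genes of the T-cell programme had called gene ends in both genotypes. The share over all protein-coding genes is not given here, and most lists of other lineages also had most of their genes called. All 18 genes of the Notch list, including Notch1, Hes1, Dtx1, Ptcra, Il2ra and Myc, had a peak within 1 kb of an annotated end in every library. The same held for all 20 T-lineage transcription factors (Gata3, Tcf7, Bcl11b, Runx1 and others), all 17 pre-TCR and TCR signalling genes and all 12 genes of antigen receptor recombination, Rag1 and Rag2 among them. Erythroid markers had 4 or 5 of 9 genes called, and neither Gata1 nor Hba-a1 was called in any library. B cell markers had 7 or 8 of 10, NK, ILC and gamma-delta markers 8 of 10, and early progenitor markers 9 of 10. Myeloid markers had 9 of 10 in wild type and 7 of 10 in mutant, and thymic stroma markers 8 and 9 of 10 in wild type and 7 in mutant. Late thymocyte genes had 10 of 13 called in wild type and 11 in mutant, Myc targets and growth genes 21 or 22 of 22, and housekeeping genes 11 of 12 in wild type and 12 in mutant.

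Regions near Notch genes were called only in wild type less often than regions elsewhere. Of 225 regions assigned to the Notch list, 13 were called only in wild type (5.78%, 95% interval 3.11 to 9.68), against 15% of other regions (odds ratio 0.348, Fisher's exact p = 3.12e-05, adjusted p = 4.37e-04). Notch3, a receptor, had 4 of the 13, and 15 of its 28 regions were called in all 4 libraries. Notch1 had 1, with 25 of 34 regions called in all 4, and Hes1 had 1 with 13 of 19. The adjusted p rose to 1 with equal numbers of peaks, 0.641 at −log10 q of 5 or more, 0.125 with 50% cover, 0.110 with a common minimum length and joining gap, 0.0817 for assignment within 10 kb and 0.0644 with equal covered length, at odds ratios of 0.312 to 0.722. At fold 4 or more the odds ratio turned to 1.59 (Fisher's exact test, adjusted p = 0.426), where a region counted as wild-type-only may hold a mutant peak of lower fold.

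No other list passed the adjusted test among regions called only in wild type. By Fisher's exact test, the share was 12.6% of 461 regions for T-lineage transcription factors (adjusted p = 0.474), 9.45% of 201 for pre-TCR and TCR signalling (adjusted p = 0.146) and 8.13% of 123 for late thymocyte genes (adjusted p = 0.146). For pre-TCR and TCR signalling the odds ratio was 0.593, with 0.624 without wild-type replicate 2 and 0.559 without mutant replicate 1. For late thymocyte genes these were 0.503, 0.476 and 0.433. Recombination genes had 11.5% of 78 regions (exact test, adjusted p = 0.917), Myc targets 14.0% of 107 (adjusted p = 1) and housekeeping genes 14.3% of 70 (adjusted p = 1). Among lists of other lineages the share ran from 4.17% of 24 regions for erythroid markers to 17.7% of 141 for early progenitor markers, with adjusted p of 0.572 and 0.690. It was 16.3% of 49 for B cell markers, 12% of 75 for myeloid markers, 13.7% of 95 for NK, ILC and gamma-delta markers and 13.9% of 79 for thymic stroma markers. By the exact test within deciles of strength, 4 lists had fewer wild-type-only regions than others of like strength, namely the Notch list (odds ratio 0.175, adjusted p = 7.12e-12), T-lineage transcription factors (0.391, adjusted p = 1.51e-10), pre-TCR and TCR signalling (0.362, adjusted p = 1.04e-04) and late thymocyte genes (0.359, adjusted p = 0.010). For T-lineage transcription factors the direction turned at fold 4 or more, with an odds ratio of 2.23 (exact test, adjusted p = 0.012). In that setting too, a region counted as wild-type-only may hold a mutant peak of lower fold. For regions called only in mutant, 0 of 14 lists passed the adjusted Fisher's exact test and 2 had an unadjusted p under 0.05. These were T-lineage transcription factors, with 13 of 406 regions (odds ratio 1.86, exact test, adjusted p = 0.245), and recombination genes, with 4 of 70 (3.40, adjusted p = 0.245). The transcription factor list passed when any 1 library was left out (odds ratio 1.96 to 2.20) and with equal numbers of peaks (2.39, exact test, adjusted p = 2.79e-07). Within deciles of strength its odds ratio turned to 0.935 (exact p = 1), and no list passed at −log10 q of 5 or more, at fold 4 or more, with 50% cover or with a common minimum length and joining gap.

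**Figure D4:**
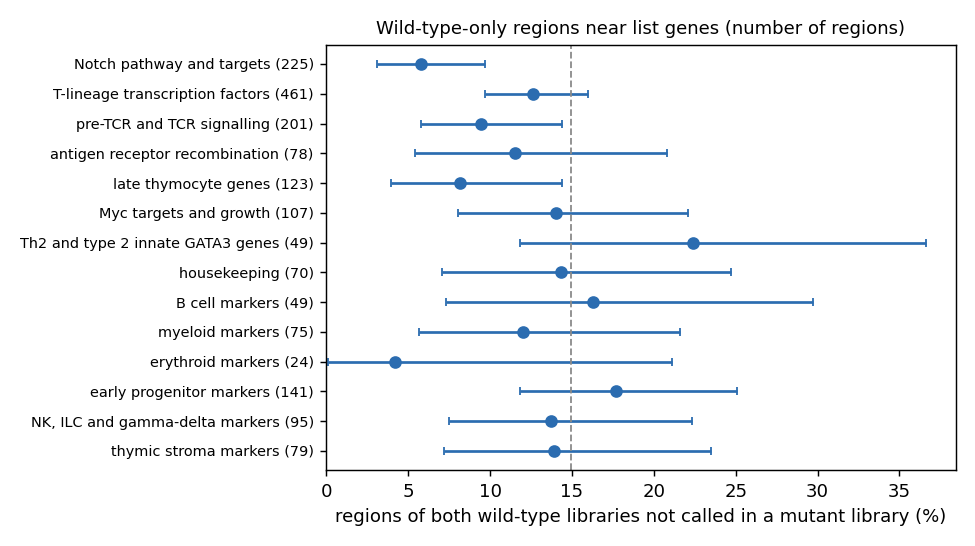
Share of regions called in both wild-type libraries that no mutant library had (%, x axis), for regions assigned to each gene list, with exact 95% binomial intervals and the number of regions in brackets; the dashed line is the share over all regions, 15%. The Notch list, at 5.78%, was the only one past the adjusted test.

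Of the type 2 cytokine locus, which GATA3 controls in T helper 2 cells, Il4, Il13 and Il5 had gene ends called in wild type only, while Rad50 had an end called in 4 of 4 libraries. Il4, Il13 and Il5 each had a narrow region of 94 to 190 bp near an annotated end in both wild-type lists, with fold from 1.82 to 2.73, and none within 1 kb in either mutant list. The closest mutant peak lay 1080 bp from the end of Il4, 1262 bp from that of Il13 and 13111 bp from that of Il5. For the whole Th2 and type 2 innate list, 11 of 49 regions (22.4%, 95% interval 11.8 to 36.6) were called only in wild type, which did not pass the test (odds ratio 1.65, exact p = 0.158, adjusted p = 0.474). Of 181 list genes, 7 had an end called only in wild type, the others being Csf1r, Mpo, Slc4a1 and Psmb11. At Csf1r the wild-type libraries had different regions near the end, and none was shared by both. Another 3, Ccr4, Actb and Ermap, had an end called only in mutant. At these 3 ends the region itself was called in all 4 libraries, and the wild-type peaks stopped 1003 to 1117 bp from the gene end, just beyond the 1 kb limit. The closest mutant peak also lay little beyond this limit at Il4, Il13, Mpo, Slc4a1 and Psmb11, and further away at Il5 and Csf1r. The share of all protein-coding genes with an end called in 1 genotype only is not given here. The 7 of 181 therefore has no genome-wide comparison.

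Regions at gene ends were less often specific to a genotype than distal regions. Of 18594 gene-end regions called in both wild-type libraries, 1160 (6.24%) were called only in wild type, against 16.4% of 116371 distal regions (odds ratio 0.340). Within deciles of strength the odds ratio was 0.582 (exact stratified p = 4.26e-58). For regions called only in mutant the shares were 0.450% of 16884 and 2.00% of 90116 (odds ratio 0.222, Fisher's exact p = 1.80e-59).

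The 10 strongest distal regions called only in wild type had a lower fold of up to 9.02, and 6 of them were under 150 bp wide. They included a 771 bp region inside Xrcc4, a gene of DNA end joining, at chromosome 13, 89998608 to 89999378 (fold 8.12 and 9.01). A 601 bp region inside Baiap2l1, nearest to an end of Bri3, lay at chromosome 5, 144267451 to 144268051 (8.32 and 8.75). A 797 bp region inside Entpd7, nearest to an end of Cox15, lay at chromosome 19, 43722698 to 43723494 (8.08 and 8.49). The region with the highest lower fold was 75 bp wide (9.02 and 9.53) and lay outside protein-coding genes at chromosome 4, 80003907 to 80003981, with the nearest gene end, of Tyrp1, 830 kb away. Others lay inside Lrp1b, Crocc2 and Stag1, 18.8 kb from an end of Camsap2 and 1536449 bp from one of Slc39a10. The regions named by Tyrp1, Lrp1b, Camsap2 and Slc39a10 were 65 to 82 bp wide. The shortest peak was 73 bp in mutant 1 and 87 bp in mutant 2. A peak as narrow as these could thus not be listed in mutant 2, nor the 65 bp one in mutant 1. At gene ends, the leading region called only in wild type was at Lsamp, a neuronal adhesion molecule (chromosome 16, 39984180 to 39985227, fold 7.10 and 7.53). It was followed by Gm3248 (2 regions), Mapkapk3, Tmem74, Olfr1382, Gm3239, Myo1h, Ptgis and Lair1, with a lower fold of 3.82 to 4.64. The regions at Olfr1382 (84 bp) and Gm3239 (71 bp) were also narrower than the shortest peak of mutant 2.

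Of the 1876 regions called only in mutant, 12 had a fold of 4 or more in both libraries, as did 184 of the 20194 called only in wild type. The leading distal region lay outside protein-coding genes, 11.7 kb from an end of Mtus2, at chromosome 5, 147945178 to 147945613 (fold 6.31 and 7.27). It was followed by a 1138 bp region inside Rhobtb3 at chromosome 13, 75930903 to 75932040 (5.39 and 7.12) and a 584 bp region inside Spef2 at chromosome 15, 9624712 to 9625295 (4.95 and 5.33). The others were nearest to Drc3, Mid1, Sh3bp5l, Klf14, Sugct, Hint1 and Pcdh7. The leading gene-end region was 1364 bp wide inside Zfp64 (chromosome 2, 168893235 to 168894598, fold 4.02 and 4.76), ahead of others at Fhl4, Ldhb, Swi5, Gm10130, Mup4, Serpina3g, Cttnbp2 and Serbp1, whose lower fold was 2.72 to 3.88.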

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

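The alternatives with a common minimum length and joining gap or with equal covered length, all those of the Myc-domain test for mutant-only regions, and the peak ratios without a replicate or within numbered pairs were chosen after the data were seen. Of 114 alternatives over all results, 78 kept direction and side of the threshold, or stayed within the allowed spread or 1.5 times the count. N-Me was called in every library used in 11 of 11, which its strong peaks fixed in advance. The gene-end against distal odds ratio stayed below 1 with exact p under 0.05 in 13 of 13. The cause of the changes below was not tested, except that fewer libraries or peaks change counts by construction.

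Regions called only in wild type, 20194 as reported, numbered 9237 at −log10 q of 5 or more, 10671 at fold 4 or more and 5086 with equal numbers of peaks. These are not subsets of the 20194, since peaks were filtered before calling and a weaker mutant peak may have been dropped. Of the 20194, 184 had fold 4 or more in both wild-type libraries. Leaving out a replicate gave 26342 to 40864, the extremes being without mutant replicate 2 and without wild-type replicate 2, and 31182 without wild-type replicate 1. Regions called only in mutant, 1876 as reported, numbered 603 at fold 4 or more, 7423 with equal numbers of peaks and 6901 with 50% cover. Without a replicate they numbered 2740 to 4940, namely 3918 without wild-type replicate 1, 4539 without mutant replicate 1 and 4940 without mutant replicate 2. The ratio of peak numbers, 1.36, was 1.23 at −log10 q of 5 or more, 1.24 with a common minimum length and joining gap, and 1 by construction with equal numbers. The excess of the Jaccard index within genotypes, 0.101, was 0.139 at fold 4 or more and 0.0914 with a common minimum length and joining gap.

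The Myc-domain odds ratio for wild-type-only regions, 0.874, turned to 1.36 at −log10 q of 5 or more, 1.2 at fold 4 or more, 1.42 with equal numbers of peaks and 1.06 with 50% cover, with no exact p under 0.05 in any alternative. For mutant-only regions it was 4.71 at fold 4 or more (exact p = 0.0741, from 2 regions), 3.15 with 50% cover, 3.93 with equal numbers of peaks and 3.11 to 6.60 without a replicate, the lowest without mutant replicate 1. Among regions called only in wild type, the number of lists past the adjusted test, 1 as reported, was 4 within deciles of strength, and 1 to 3 without a replicate, with 3 without wild-type replicate 2 and without mutant replicate 1. It was 0 with equal numbers of peaks (0 unadjusted), 50% cover (2 unadjusted), a common minimum length and joining gap (2), equal covered length (3) and assignment within 10 kb (1). At −log10 q of 5 or more and at fold 4 or more the 1 list was that of T-lineage transcription factors, with odds ratios of 0.358 and 2.23. The Notch odds ratio was 1.59 at fold 4 or more.

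With the replicate number as a block, regions present in the wild-type and absent from the mutant library of both numbered pairs were the same 20194 by construction. The ratio of peak numbers within pairs was 1.40 and 1.31 (mean 1.36). The Jaccard index was 0.673 within numbered pairs and 0.676 in the crossed pairing, and the libraries share only a number. The GATA motif comparison and its alternatives were not run. Unknown read depth limits every absence of a peak.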

Other observations

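Tests chosen only after the result was seen were those of background depth, of windows along the genome, of the flanks of the Myc domain, and both tests of the N-Me edge. Over the genome, 11.2% of regions were wild-type-only and 1.04% mutant-only. Within the T-lineage transcription factor list, Bcl11b, a factor of T-cell commitment, had 11 wild-type-only and 3 mutant-only regions among 77, with 39 called in all 4 libraries. Ets1 had 10 wild-type-only regions among 53 and Runx1 had 7 among 61, and neither had a mutant-only region. Tcf12, an E protein, had 3 of each kind among 38. Gata3 had 1 wild-type-only region among 29, with 16 called in all 4. These genes were chosen after their values were seen.

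Among regions with fold 3 or more in both libraries that had them, 8 of the 14 shared only by wild type 1 and mutant 1 lay on chromosome 6, which held 5.58% of all regions of that strength. Chromosome 12, with 4.57% of them, held 6 of the 15 shared only by wild type 1 and mutant 2 and 4 of the 9 shared only by wild type 2 and mutant 1. Of 92 such mutant-only regions, 10 lay on chromosome 11, which held 6.98% of all regions of that strength. Of 2027 such wild-type-only regions, 167 lay on chromosome 9 (5.53%), and 2 of the 5 shared only by wild type 2 and mutant 2 on chromosome 16 (3.53%). Each chromosome was named because it held the most regions of its pattern, so a share above the genome-wide one is to be expected.

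Regions called only in wild type outnumbered those called only in mutant, with 20194 against 1876. A different minimum length and joining gap of the lists is argued against as the whole cause, since the ratio was 6.56 with both made common. Both were made common in finished lists only, so other effects of differing settings on the calls were not tested. The greater number of wild-type peaks stays open, since the ratio was 0.685 with the same number from each list, a match that pushes it towards balance by construction, and 11.4 with the same covered length. A lower background depth in mutant libraries stays open too, since depth is not recorded. At matched fold (2.8 to 2.85, peaks under 200 bp) the lowest mutant median −log10 p lay 0.19 above the highest wild-type one. That was less than the 0.86 between replicates. Listed peaks had already passed the q threshold, so peaks that low depth would drop are missing from this comparison, and it cannot decide. An effect of genotype stays open and untested, and 2 libraries per genotype allow no share of splits below 0.333.

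Mutant-only regions were in excess in the Myc domain, and the 10 of them lay between Myc and N-Me. The values below are for the whole 2 Mb domain. Among its 166 regions, 10 were called in mutant 1 alone and 1 in mutant 2 alone. Genome-wide these patterns made up 1.59% and 1.4% of regions. A local difference between the mutant libraries was not tested. Chance placement stays open. Elsewhere, 9 of 1078 overlapping windows of 2 Mb (0.835%) with a like number of regions held as many, the highest count being 12. That share makes no allowance for taking up this direction after its excess was seen, so it cannot decide. A difference in joining is argued against as the whole cause, since the odds ratio was 4.85 with a common minimum length and joining gap. A strain segment carried along with the edited allele may contribute, since the 10 Mb on each side also held an excess (odds ratio 2.17, 95% interval 1.43 to 3.17, Fisher's exact p = 2.55e-04), though a smaller one than the domain (odds ratio 2.85 for domain against flanks, Fisher's exact p = 0.00935). The flanks also held fewer wild-type-only regions than elsewhere (97 of 876, odds ratio 0.706, Fisher's exact p = 8.71e-04). An effect of the enhancer mutation on the Myc domain is a hypothesis that these data leave open.

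The left edge of the N-Me peak lay at least 175 bp further in for both mutant libraries. Edge scatter stays open: 579 of 34320 edges (1.69%) of shared peaks of like width lay inward by as much, but this edge was chosen because it stood out, and 13.7% of such peaks had either edge apart by as much in either direction. That 13.7% includes outward shifts, which longer mutant joining gaps can also give, so it does not measure inward scatter. Over the left edges of these peaks the median inward shift was −57 bp, that is, outward. A difference in joining is argued against, since the mutant lists had the longer gaps, which can only extend a peak, while the edge lay inward by more than the 110 bp between replicates. Giving all lists a common minimum length and joining gap moved no left edge here, which left the shift at 175 bp and decides nothing by itself. Loss of accessibility at the mutated GATA sites is a hypothesis, and loss of reads that span the altered bases may give the same edge, which the reads and edit positions, not used here, are needed to tell.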
